A study of Mus musculus with 24 samples.

How the data were processed

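Total RNA of the tibialis anterior muscle, a muscle of the lower leg, was measured on 1-colour microarrays in 8 mice aged 6 weeks of a mixed C57BL6/J;129S1/SvImJ background. Per the labels, 5 micrograms of Cy5-labelled RNA were used, and the RNA was extracted with Trizol from frozen muscle. The 4 control animals carried the Myf6 cre driver, which is active in muscle fibres, with a floxed and an intact Hira allele. The 4 animals labelled Hira CKO (conditional knockout) carried the same driver with a floxed and a null Hira allele. Each animal was hybridised on 3 arrays, giving 24 arrays. The animal was the replicate, and the 3 arrays of an animal were repeats of 1 RNA.

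The deposited table held a linear intensity for each of 26423 probes on each array. The values had been normalized by the authors, as judged from the table: array medians lay between 431.5 and 433.5, the highest value was 439069.7 on every array, and 81.1% of the values were whole multiples of 1/24 within 0.001, as quantile normalization over 24 arrays gives. Background had evidently been subtracted, since 50 values were at or below 0 and the lowest was −12.9. The scanner, the background method and the software were not given in the sources used here. The table carried no detection calls, so dim probes were kept, and the number of arrays limits the precision. No slide or scan date was given, so array batch and group cannot be told apart. Sex was not given in the labels.

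Probes were named from the platform annotation, which gave 1 symbol to 20377 probes and several symbols to 0. The other 6046 probes are unnamed here. Symbols were updated with the RefSeq gene table of the assembly GRCm38.p6: 18213 were current, 2126 were found as a synonym and 38 were kept as given. The probes named 17742 distinct genes. The table was used only for names and for the order of neighbouring genes, because no genome build was named for the array.

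The planned test was on log2 values. The deposited values were linear, so values below 0 were set to 0, a pseudocount of 16 was added and log2 was taken. The pseudocount was chosen once the unit was known and before any test was run. Fold changes are on this log2(value + pseudocount) scale and understate the change of dim probes. The 3 arrays of an animal were averaged, and the groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), with Benjamini-Hochberg adjustment over all 26423 probes and a threshold of 0.05 on the adjusted p, which is the p quoted for single genes. Intensities are given as mean ± SD of 4 animal means. For Hira an exact two-sided permutation test over the 70 assignments of the animals was added.

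Fixed gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, on the probe with the highest mean for each gene, where at least 5 members were measured. Benjamini-Hochberg adjustment was over the 33 lists tested. Camera with an estimated correlation and fry were also run. For array-level, weighted and trended fits, cameraPR was applied to the moderated statistics. The fry test asks whether a list's genes move on balance in 1 direction and does not compare them with other genes.

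The design, the gene lists, the alternatives listed below and the rule for named genes were set before the data were examined. The rule named Hira and the HIRA complex, then the 10 largest rises and the 10 largest falls. These came from probes that passed the threshold, had 1 symbol and did not overlap between the groups. For these rises and falls each gene was taken at its probe with the smallest p, which need not be its brightest. The rule then took up to 4 members of each list with the largest change among those that passed, at their brightest probe. Genes outside it are said to have been chosen after their values were seen. The rule gave 110 genes.

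The alternatives were other normalizations, a filter on the lowest 30% of probes, other treatments of the 3 arrays, the animal number as a block, other variance models, array weights, each animal or repeat left out, pseudocounts of 1, 10 and 50, other thresholds, a Welch test per probe, and other gene list tests. The fit was tested on simulated data with 26423 probes and known changes. It recovered 49.3% of 67 changes of 0.5 log2, 92.5% of 67 changes of 1 log2 and 98.5% of 66 changes of 2 log2. There were 10 false calls among unchanged probes. With no change simulated the fit made 0 calls. Simulated errors were independent between probes, and far fewer probes were changed than passed in the data. The simulation therefore does not give the rate of false calls in the data. Figures were drawn with matplotlib 3.10.9.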

Results

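Expression in tibialis anterior muscle was compared between 4 control mice and 4 mice labelled Hira CKO at 6 weeks of age. Where cre is active, fibres would keep the intact Hira allele in controls and no intact allele in Hira CKO. Cells without cre also differ between the groups, by an intact or a null allele beside the floxed one. The comparison is therefore not of deletion in muscle fibres alone. Hira encodes a chaperone that deposits the histone variant H3.3. The 24 arrays, 3 per animal, had the same distribution of intensities. Values of 2 arrays of the same animal correlated at a median of 0.994 across probes, animals of 1 group at 0.989 and animals of different groups at 0.981. The median SD was 0.130 log2 between single arrays of an animal and 0.136 log2 between the animal means of a group. Each animal mean averages 3 arrays, which lowers array error, so the 2 values are not like measures. With group in the model, the limma consensus correlation of arrays of an animal was 0.40.

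The Hira probe was not lower in the animals labelled Hira CKO. Its intensity was 495 ± 48.9 (SD, n = 4) in controls and 558 ± 38.9 (SD, n = 4) in Hira CKO. The difference was 0.17 log2 (SE 0.087, 95% interval −0.02 to 0.36), with a limma adjusted p of 0.193 and an exact permutation p of 0.114, where 0.0286 is the smallest p the design can give. Where the probe lies relative to the deleted part was not given in the sources used here, and a probe outside that part checks nothing. The directions below therefore rest on the group labels.

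**Figure D1:**
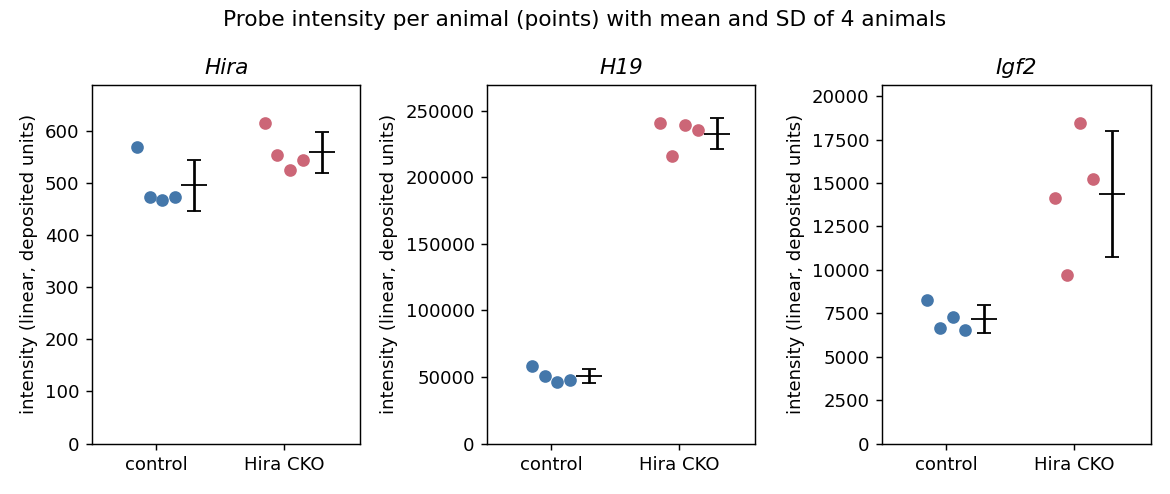
Linear probe intensity of Hira, H19 and Igf2 in each of 4 control and 4 Hira CKO animals (points, means of 3 arrays), with the mean and SD of the group beside them. H19 lay between 46144.1 and 58177.9 in controls and between 215676.9 and 240410.4 in Hira CKO, while the groups overlapped for Hira.

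The imprinted RNA gene H19 had the largest rise among the genes named by rule. Its intensity went from 50729 ± 5315 in controls to 232679 ± 11520 in Hira CKO (SD, n = 4), a change of 2.20 log2 (SE 0.087, limma adjusted p 2.35e-06). Its neighbour Igf2, a growth factor gene, rose by 0.95 log2, from 7186 ± 795 to 14368 ± 3621. The largest fall was in Phka1, the muscle regulatory subunit of phosphorylase kinase, which releases glucose from glycogen through phosphorylase. Phka1 went from 6260 ± 2081 to 551 ± 125, a change of −3.45 log2 (SE 0.258, limma adjusted p 3.04e-05). Phkg1, the catalytic subunit of the same enzyme, fell by 1.44 log2.

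The other large rises were in Tecta (2.09 log2), a protein of the inner ear, Pnmt (2.09), which makes adrenaline, H4c9 (2.03), a replication-dependent histone H4 gene, Rom1 (2.00), a protein of photoreceptor membranes, Rab15 (1.99), a small GTPase, Bdh1 (1.97), an enzyme of ketone body use, Tlcd2 (1.97), Exoc3l4 (1.93) and A530095I07Rik (1.92). Sequences of histone H4 genes are nearly identical, and the H4c9 value is uncertain for that reason. The other large falls were in Rap1gds1 (−3.31 log2), Abcc5 (−3.07), a transporter, Aimp2 (−3.07), a scaffold of the tRNA synthetase complex, Gar1 (−2.86), a protein of RNA-modifying particles, Npepl1 (−2.81), Wdr43 (−2.74), Mzt2 (−2.65), Cbll1 (−2.63) and Stard8 (−2.63). For 3 of these genes a second probe did not pass: Rap1gds1 changed by −0.05 log2 at its second probe, Aimp2 by −0.22 and Wdr43 by 0.08. That second probe was the brighter one for Rap1gds1 (mean of 11906 against 3684 in controls) and for Wdr43 (637 against 459). The probe that the list tests would use thus showed no called change for Rap1gds1 and Wdr43. The probes of Phka1 and Aimp2 lay in a stretch of 1000 consecutive probe numbers that held 24 of the 100 largest falls. The fall of Cbll1 ended at an intensity of 29.1, near the pseudocount.

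In all, 5432 of 26423 probes (20.6%) passed in limma, 2783 higher and 2649 lower in Hira CKO. They covered 2113 genes with a higher and 2078 with a lower probe, of which 43 had both. The median size of a called change was 0.45 log2. A fold of at least 2 was seen for 146 higher and 295 lower probes, and a fold of at least 4 for 6 and 51. The groups did not overlap for 6552 probes (24.8%), against 2.86% by chance. The first principal component of the arrays held 35.7% of the variance, with control arrays from −39.1 to −21.8 and Hira CKO arrays from 23.7 to 33.0. The count of higher probes was 1841 without Hira CKO animal 1. Among 1970 genes with exactly 2 probes, the changes at the 2 probes correlated at 0.19 across genes, which are not independent replicates. For single animals, deviations from the group mean correlated at 0.17 to 0.31 between the 2 probes, and mean levels correlated at 0.38. Of 700 such genes with a called probe 113 had both called. The number that unrelated probes would give was not computed, so 113 does not by itself show that the 2 probes of a gene agree.

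**Figure D2:**
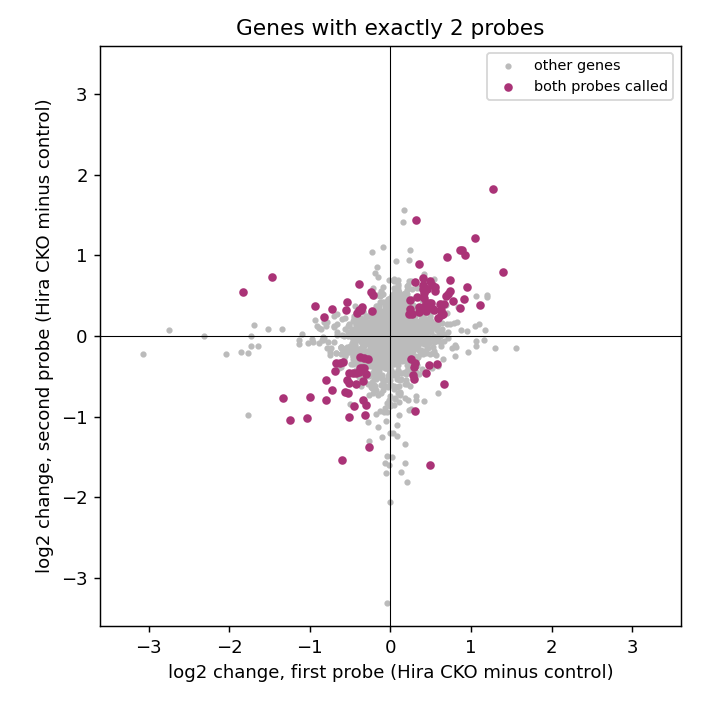
Log2 change (Hira CKO minus control) at the first and second probe of 1970 genes with exactly 2 probes, each point a gene. Of 113 genes with both probes called (dark points), 87 had the same sign, and many large changes at 1 probe lay near 0 at the other.

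Of 33 lists fixed beforehand, camera called 2, both lower in Hira CKO. Across these lists the median share of members past the threshold was 20%. Over all genes, 21.2% of the brightest probes passed. A count of called members near that share does not set a list apart from other genes. An adjusted p given for a list is from camera unless fry is named. For the genes that neighbour Hira on chromosome 16, 0 of 20 measured members rose and 6 fell (8 adjusted over the list alone), with a median of −0.23 log2 and an adjusted p of 0.0108. With an estimated correlation the adjusted p was 0.288. Tbx1, a transcription factor gene, fell by 1.03 log2 at its brightest probe and changed by −1.02 at a second. Ufd1 fell by 0.30 log2, a call lost without control animal 3. Arvcf fell by 0.58 log2 and Ess2 by 0.51, although a second Ess2 probe changed by −0.16 and did not pass. Gp1bb, named after its values were seen, counts among the 6 through its brightest probe (−0.29 log2), while its other probe was called higher (0.25 log2, adjusted p 0.0333).

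For glycolysis and glycogen genes, 0 of 13 measured members rose and 4 fell (4 adjusted over the list alone), with a median of −0.14, a mean of −0.48 log2 and an adjusted p of 0.0108. With an estimated correlation the adjusted p was 0.446. The 4 were Phka1, Phkg1, Pfkm (phosphofructokinase, −0.31 log2) and Pkm (pyruvate kinase, −0.27), whose call was lost in 4 of 8 fits that left out 1 animal. The call rested on Phka1: without it the adjusted p was 0.0761, and without Phka1 and Phkg1 it was 0.237, and without the probe stretch that held Phka1 it was 0.0588, all tried after the values were seen. With only array 1 of each animal it was 0.117.

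The test fry, which does not compare a list with other genes, called 10 lists. Besides the 2 above, these were other histone chaperones (adjusted p 0.0074), lymphocyte markers (0.0075), cytosolic ribosomal protein genes (0.0170) and embryonic and regenerating fibre genes (0.0249), all higher in Hira CKO, and genes of ER stress and the integrated stress response (0.0074), sarcolemma and membrane repair genes (0.0243), muscle ion channel and pump genes (0.0249) and smooth muscle and pericyte markers (0.0249), all lower. The median and mean change of a list differed in sign for embryonic fibre (−0.03 and 0.03 log2), fast fibre (−0.05 and 0.0015) and fatty acid use genes (0.01 and −0.02). Whether the fry calls rest on single genes with large changes was not tested.

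The number of called members of a list also depended on single animals. Over the 8 fits that left out 1 animal, the falls ranged from 4 to 6 among genes that neighbour Hira, 0 to 2 among slow fibre, growth signalling and p53 target genes, 2 to 4 among sarcolemma and membrane repair genes, 1 to 2 among oxidative phosphorylation genes, 1 to 4 among cell cycle genes, 3 to 5 among endothelial markers and 1 to 3 among interferon response genes. The rises ranged from 0 to 3 among ion channel and pump genes, 3 to 4 among oxidative phosphorylation genes, 2 to 4 among cell cycle genes, 1 to 4 among lymphocyte markers and 0 to 5 among circadian clock genes. Other counts of rises or falls changed by at most 1.

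Of 5 measured genes of the HIRA complex and H3.3, Ubn2 rose by 0.39 log2 (adjusted p 0.0405), a call lost in 5 of 8 fits that left out 1 animal. The changes of Ubn1 (0.01), Asf1a (−0.01), Cabin1 (−0.08) and H3f3b (0.01) did not pass. Of 9 other histone chaperones 3 rose and 2 fell, the same adjusted over the list alone. Asf1b rose by 1.81 log2, from 159 ± 13.9 to 594 ± 24.1. Nasp rose by 0.64 and Hjurp by 0.54, with second probes at 0.16 and −0.0001 that did not pass, and Dek fell by 0.47. The list was called higher by fry and not called by camera (adjusted p 0.551).

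Camera called none of the fibre type lists, and fry called the embryonic list higher. Of 10 slow fibre genes 3 rose and 2 fell (3 and 3 adjusted over the list alone). Casq2, the calcium-binding protein of the slow sarcoplasmic reticulum, rose by 1.03 log2 and Sln, an inhibitor of the calcium pump, by 0.99. Csrp3, a protein of the Z-disc, fell by 1.42 log2, the largest change among members that passed, and lost its call in 6 of 8 fits that left out 1 animal. Atp2a2, the slow calcium pump, rose by 1.27, with 2 further probes at 0.21 and 0.47 that did not pass. Of 9 fast fibre genes 1 rose and 0 fell (0 and 0 adjusted over the list alone). The rise was in Casq1 (0.25 log2), whose call was lost in 7 of 8 fits that left out 1 animal and whose second probe changed by −0.23 and did not pass. Of 12 embryonic and regenerating fibre genes 3 rose, H19 and Igf2 among them, and 2 fell, the same adjusted over the list alone. Actc1, cardiac actin, fell by 2.21 log2 and Chrng, the fetal acetylcholine receptor subunit, by 0.68. The adjusted p was 0.714 for slow, 0.966 for fast and 0.759 for embryonic fibre genes.

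Of 18 cytosolic ribosomal protein genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), with Rpl5 at 0.95, Rpl14 at 0.72 and Rps3 at 0.64 log2, and an adjusted p of 0.107. Camera called this list higher in 5 of 31 other settings (adjusted p 0.0150 to 0.0303). With an estimated correlation its adjusted p was 0.819. Of 31 oxidative phosphorylation genes 5 rose and 3 fell (5 and 4 adjusted over the list alone), with Cox7a1 at 0.72 and Ndufb5 at −0.71 log2 (adjusted p 0.837). Of 16 fatty acid use genes 0 passed, over all probes or adjusted over the list alone (adjusted p 0.966). Of 20 genes of ER stress and the integrated stress response 1 rose and 2 fell (1 and 1 adjusted over the list alone), where the chaperone gene Calr fell by 2.26 log2 and the chaperone gene Hspa5 rose by 0.61 (adjusted p 0.551). Of named genes in these lists, Atp5o (0.50 log2) and Asns (−0.66) lost their calls in 5 and 6 of 8 fits that left out 1 animal.

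Of 19 sarcolemma and membrane repair genes 1 rose and 5 fell (1 and 8 adjusted over the list alone), with Anxa5 at −0.95 and Cav3, the muscle caveolin, at −0.89 log2 (adjusted p 0.237). The rise was in Dag1, named after its values were seen (0.23 log2, limma adjusted p 0.0441). Its other probe was called lower (−0.83 log2, limma adjusted p 0.00775). Of the falls, Flnc (−0.48 log2) and Trim72 (−0.36) lost their calls in 6 and 4 of 8 fits that left out 1 animal. Of 22 ion channel and pump genes 1 rose and 3 fell, the same adjusted over the list alone (adjusted p 0.237). Stim1, a calcium sensor, fell by 0.67 log2 and at a second probe by 0.33, the potassium channel gene Kcnc4 fell by 0.52, and Slc8a3, a sodium-calcium exchanger gene, rose by 0.41, a call lost without control animal 3. The call of Cacnb1 (−0.33 log2) was lost in 6 of 8 fits that left out 1 animal, and of 2 further probes 1 passed (−0.64) and 1 did not (−0.26). Of 14 neuromuscular junction genes 3 rose and 2 fell, the same adjusted over the list alone, with Lrp4 at 0.81, Ache at 0.60, Chrng at −0.68 and Rapsn at −0.39 log2 (adjusted p 0.714). The call of Rapsn was lost in 6 of 8 fits that left out 1 animal. Of 14 growth signalling genes 2 rose and 2 fell (3 and 3 adjusted over the list alone), with Akt1 at 0.78, Smad7 at 0.63, Gdf11 at −0.46 and Acvr2b at −0.41 log2 (adjusted p 0.714). The calls of Gdf11 and Acvr2b were lost in 4 and 5 of 8 fits that left out 1 animal.

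Camera called none of the lists of markers of other cell types in dissected muscle, and fry called lymphocyte markers higher and smooth muscle and pericyte markers lower. Of 13 endothelial markers 1 rose and 5 fell, the same adjusted over the list alone, with Egfl7 at −0.69, Kdr at −0.60 and Eng at 0.55 log2 (adjusted p 0.237). Of 10 smooth muscle and pericyte markers 0 rose and 2 fell, the same adjusted over the list alone, with Rgs5 at −1.11 log2 (adjusted p 0.536). Of 12 lymphocyte markers 4 rose and 1 fell, the same adjusted over the list alone, with Cd3e at 0.48 and Il7r at −0.44 log2 (adjusted p 0.237). Of 14 macrophage markers 1 rose and 1 fell, the same adjusted over the list alone, where Cx3cr1 fell by 1.61 and Itgam rose by 0.40 log2 (adjusted p 0.653). The calls of Il7r and Itgam were each lost in 6 of 8 fits that left out 1 animal, and those of the lymphocyte markers Cd79b (0.29 log2) and Cd4 (0.34) in 7 and 2, and that of the smooth muscle marker Smtn (−0.41) in 2. Of 20 extracellular matrix genes 0 rose and 2 fell, the same adjusted over the list alone, namely Col4a1 at −0.66 and Col4a2 at −0.48 log2 (adjusted p 0.551). Of 10 satellite cell markers 1 rose and 1 fell (1 and 4 adjusted over the list alone), with Megf10 at 0.53 and Sdc3 at −0.32 log2 (adjusted p 0.551).

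Of 16 interferon response genes 0 rose and 3 fell, the same adjusted over the list alone, with Psmb8, a subunit of the immunoproteasome, at −1.52 log2 (adjusted p 0.237). The other falls, in Isg15 (−0.63 log2) and Irf7 (−0.55), each lost their call in 5 of 8 fits that left out 1 animal. Of 19 cell cycle genes 2 rose and 4 fell (3 and 4 adjusted over the list alone), with the mitotic kinase gene Aurka at 1.18 and Ccne1 at −0.63 log2 (adjusted p 0.759). The call of Mcm2 (−0.37 log2) was lost in 6 of 8 fits that left out 1 animal. Of 25 NRF2 and oxidative stress genes 3 rose and 2 fell (4 and 2 adjusted over the list alone), with Gpx1 at 0.65, Prdx1 at 0.56 and Nqo1, a target of NRF2, at −0.40 log2 (adjusted p 0.759). The calls of Nqo1 and Gsta3 (0.76 log2) were lost in 4 and 5 of 8 fits that left out 1 animal. Of 11 heat shock genes 2 rose and 1 fell, the same adjusted over the list alone, with Hspe1 at −0.51, Hspb6 at 0.34 and Hspb1 at 0.36 log2, a call lost in 5 of 8 such fits (adjusted p 0.837). Of 15 p53 target genes 1 rose and 0 fell, the same adjusted over the list alone, namely Ccng1 at 0.70 log2 (adjusted p 0.866). Of 14 circadian clock genes 2 rose and 1 fell, the same adjusted over the list alone, with Nr1d1 at 0.86, Hlf at 0.72 and Ciart at −0.66 log2 (adjusted p 0.714). The calls of Nr1d1 and Hlf were lost in 3 and 6 of 8 fits that left out 1 animal.

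Of 17 denervation and atrophy genes 0 rose and 1 fell (0 and 0 adjusted over the list alone), with an adjusted p of 0.966. The fall, in Ctsl (−0.37 log2), lost its call in 6 of 8 fits that left out 1 animal, and a second probe changed by 0.59 and did not pass. Of 16 immediate early genes 0 rose and 1 fell, the same adjusted over the list alone (adjusted p 0.237), namely Btg2 at −0.28 log2, a call lost in 2 of 8 such fits, with a second probe at −0.09 that did not pass. Of 11 fibro-adipogenic progenitor markers 0 rose and 1 fell (0 and 0 adjusted over the list alone, adjusted p 0.542), namely Pi16 at −0.43 log2, a call lost in 7 of 8 fits that left out 1 animal. Of 12 adipocyte markers 1 rose and 0 fell, the same adjusted over the list alone, namely Adig at 0.67 log2 (adjusted p 0.838). Of 10 neutrophil markers and 9 nerve and Schwann cell markers 0 passed either way, with an adjusted p of 0.966 and 0.551. Of red blood cell genes 4 were measured, too few for the list test, and 0 passed.

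**Figure D3:**
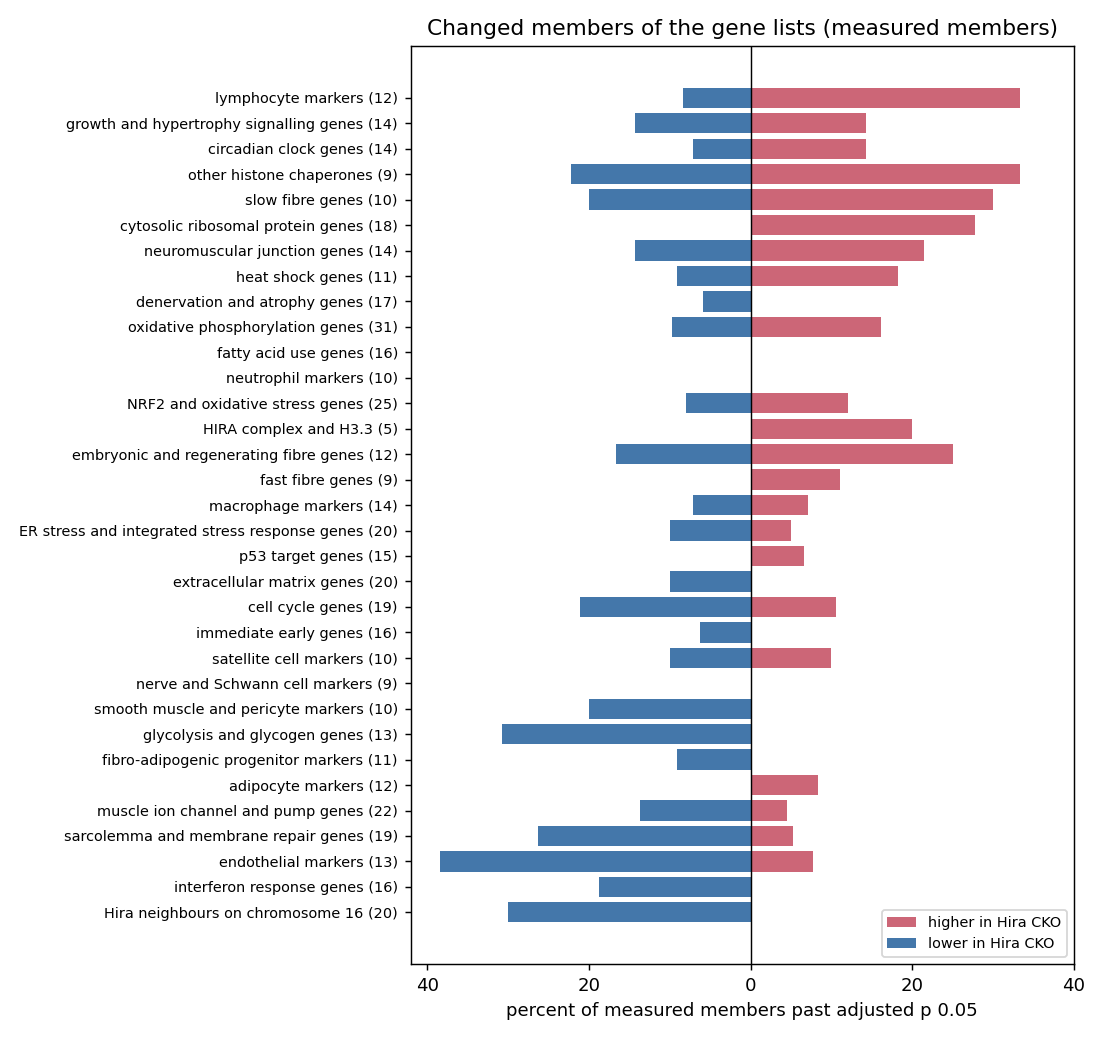
Percent of the measured members of 33 gene lists that passed the threshold in limma, lower in Hira CKO to the left and higher to the right, with the number of measured members in brackets and lists ordered by median log2 change. Among genes that neighbour Hira, 6 of 20 fell and 0 rose, while fatty acid use genes, neutrophil markers and nerve markers had 0 changed members. Over all genes, 21.2% of the brightest probes passed.

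The Y-linked gene Kdm5d was lower in Hira CKO (−0.75 log2), at 750 ± 52.6 in controls and 452 ± 103 in Hira CKO (SD, n = 4), without overlap. Xist was 0.19 log2 lower and did not pass. Kdm5d read 308.2 in Hira CKO animal 4, against 449.4 to 539.9 in the other Hira CKO animals.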

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

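Among 220 groups of 4 animals examined for the genes named by rule, 15 held 1 animal far from the others, where chance gives about 1 in 20. The numbers are that animal's gap to its nearest neighbour as a share of the group's range, on the log2 scale. In controls, animal 1 was highest for Hira (0.938), Itgam (0.876) and Sln (0.894) and lowest for Isg15 (0.873) and Stard8 (0.938). Control animal 2 was lowest for Dek (0.875) and Ubn1 (0.978), and control animal 3 was lowest for Pfkm (0.86). In Hira CKO, animal 1 was highest for Irf7 (0.865), animal 2 was highest for Acvr2b (0.953) and lowest for Gpx1 (0.843), and animal 3 was highest for A530095I07Rik (0.893). Hira CKO animal 4 was highest for Cacnb1 (0.865) and Exoc3l4 (0.833) and lowest for Ubn2 (0.845). For Hira, control animal 1 read 568.5 against a mean of 470.8 for the other controls.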

How the results depend on the processing

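The test without the stretch of probe numbers and the list tests without Phka1, Phkg1 or Tbx1 were chosen after seeing the data. Of the 5432 probes called (2783 higher, 2649 lower), the number rose to 11723 (6108 and 5615) with 24 arrays taken as independent, which overstates replication. It was 3191 (1522 and 1669), 2848 (1269 and 1579) and 3124 (1577 and 1547) with only array 1, 2 or 3 of each animal, 1648 (715 and 933) with a fold of at least 1.5, and 2607 (1294 and 1313) with the Welch test. Leaving out 1 animal gave 3680 to 5133 probes, 1841 to 2634 higher and 1817 to 2499 lower. No probe called both here and in an alternative fit had opposite signs. The Hira difference ranged from 0.126 log2 without Hira CKO animal 1 to 0.237 without control animal 1 (limma adjusted p 0.0626). With array weights it was 0.214 (limma adjusted p 0.0754). Hira passed only with independent arrays (limma adjusted p 0.0242), where the difference was 0.17056 log2 as in the main fit. Of the 2 lists called, 1 was left with array 1 only, without the probe stretch, without Phka1, and without Phka1 and Phkg1. The number was 0 with an estimated correlation and 10 with fry. Leaving out 1 animal gave 2 to 3 lists. The third was cytosolic ribosomal protein genes, higher without control animal 3, with the animal as a random block (with or without the repeat number), with independent arrays and with only array 3. The neighbour list kept its call without Tbx1 (adjusted p 0.0262). Of 105 called genes named by rule besides Hira, 57 kept the call in each of up to 26 other fits that gave the gene a value (the Welch test and other thresholds were counted over probes only), and 75 kept it whichever animal was left out. The cause of these differences was not tested. With the animal number as a replicate block the count was 4925. Animals with the same number correlated at 0.30, 0.09, −0.06 and 0.07 in their deviations, and only animal 1 matched its own number best. These values did not show that the numbers pair animals, and they do not exclude it. Sex as a covariate was not run, because Xist and Kdm5d gave no clear split by sex within the groups. Kdm5d differed between the groups without overlap, so a covariate taken from it could not be told apart from group. Dim probes, with no detection calls, limit what small changes mean.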

Other observations

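The tests in this part were chosen after the result was seen, or had their bounds or gene lists changed then, except the splits of the animals, the chromosome of the clustered genes and the test of other imprinted genes.

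Some genes that the rule did not name, chosen here after their values were seen, changed alike at 2 probes. Pdlim7, a protein of the muscle cytoskeleton, changed by −1.24 and −1.04 log2, and Zfp385b by −1.33 and −0.77. Hcfc1r1 changed by 1.04 and 1.22 log2, Gprc5b by 1.27 and 1.83, and Col24a1, a collagen gene, by 0.92 and 1.00. Gadd45b changed by 0.70 and 0.99 log2 and Jak1 by −0.57 and −0.69, all with both probes past the threshold in limma. Of 113 genes with both probes called, 26 changed in opposite directions. Eif4b, also chosen after its values were seen, changed by −1.83 log2 at 1 probe and by 0.54 at the other, both called.

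For the number of called probes, 1 of 35 splits of the animals gave as many as the real one, the real split itself. It gave 5432, and the highest other split gave 6. That share is the smallest the design can give, so it argues against chance assignment but cannot exclude it. Every other split mixed animals of both groups, which widens the spread, so the gap between the counts does not measure the strength of evidence. Other tables point in 2 directions. There were 7 called changes of at least 1 log2 in genes with 2 probes of like level. The median change of the partner was 0.0396 of the called change (95% interval −0.084 to 0.217). Partners were called in the same direction for 2 of 7, and for 19 of 73 over all levels. The 73 are called changes and not genes. A gene called at both probes with changes of at least 1 log2, such as Tbx1, counts once for each probe, which raises the agreement. Many changes of this size may thus belong to the probe and not to the whole transcript. A difference between arrays of the groups or an exon-specific or strain-specific difference could give that. The 7 were picked on 1 probe, which lowers the partner's share, and the largest was −1.69 log2, smaller than the largest changes named above. Where both probes were called the sign was the same for 76.991% of 113 genes (exact 95% interval 68.1 to 84.4), which is in line with a change of the transcript for part of the genes. A batch of arrays or hybridisations that follows the groups cannot be told apart from genotype, since no slide or date was given.

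The largest falls clustered along the probe numbers. Of the 100 largest, 24 lay in 1 stretch of 1000 consecutive numbers, against a 95th percentile of 11 when values were shuffled, and Phka1 and Aimp2 were in it. The commonest chromosome held 13.636% of the 22 placed genes, which argues against a chromosomal cluster. An effect of where or when probes were made may explain part of these falls, and a shared biological property of the genes in the stretch was not tested.

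Of 20 listed genes that neighbour Hira 6 fell and 0 rose at the brightest probe, although Gp1bb was called higher at its other probe. The list call was lost with an estimated correlation (adjusted p = 0.288), and the groups differ by design in the alleles linked to the null allele. The median of the 20 measured genes nearest to Hira was at percentile 8.753 of all such windows, and 11.196% of windows held as many called genes, so linked alleles remain open and were not shown. By the bound first set, a percentile above 5 or more than 5% of windows, both values would have counted against linked alleles. For the percentile that bound was written before the test. Both bounds were changed after the values were seen. The reason was that linked alleles can raise some genes and lower others, so a median outside the lowest 5% does not exclude them. The count of called genes takes both directions, so that reason does not cover the change of its bound. By the count, linked alleles stay open only under the later bound. The window of the 20 nearest measured genes is a different set from the 20 listed neighbours, and 7 of its genes were called. A930003A15Rik rose in that window by 1.77 log2, and Abcc5 (−3.07), named among the largest falls and 9 measured genes from Hira, and Eif2b5 (−1.82) fell. A930003A15Rik and Eif2b5 were named after their values were seen. With windows of 10, 50 and 100 genes the percentile was 44.8, 39.1 and 69.9, and 65.5%, 9.04% and 26.4% of windows held as many called genes, so both results depend on the window. Of 3 neighbours with several probes 2 had all probes lower, which is too few to weigh a probe-level difference. An effect of Hira itself on the region may also be possible.

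H19 and Igf2 share a locus, and other imprinted genes were asked whether they rose too. Of 33 measured, 0 rose and 1 fell, with a median of −0.0049 log2 at percentile 41.96 of 10000 random lists matched on level, which argues against a rise shared by imprinted genes. The value of Dlk1 had been seen before that test.

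H4c9 and Asf1b act with histone supply, and a hypothesis is that other replication-dependent histone genes rose as well. The answer depended on the list, which had not been written out in full before the test. With the linker histone genes H1f1 to H1f5, 7 of 26 genes rose and 2 fell. The largest change was a fall, of H2bc4 (−1.64 log2), named after its value was seen. The median of 0.11 log2 was at percentile 96.86 of random lists matched on level, and with every H1f gene it was at 97.65. Without them it was at 90.24, under the bound of the 95th percentile. The hypothesis therefore stays open, and near-identical sequences may let 1 probe read several histone genes.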
